A study of Homo sapiens with 18 samples.

How the data were processed

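RNA from wild-type HEK293A cells and from HEK293A cells with LATS1 and LATS2 both knocked out was measured by RNA-seq after 4 h in water, 250 uM ZnCl2 or 50 uM CdCl2. Per the labels' protocols, RNA was isolated with TRIzol and made into stranded Illumina TruSeq mRNA libraries. Each of the 6 groups holds 3 libraries, 18 in all, assigned to groups by their titles. The series' design text calls the replicates biological but does not say whether they came from separate cultures or days, so the p-values measure the spread between these 3 libraries per group, which can be smaller than that between independent experiments. Genotype and cell line cannot be told apart, since other knockout lines were not analysed here.

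The values used are read counts per Ensembl gene as the authors deposited them, in a table of the whole series and in a file per sample. STAR was used with the builds hg38 and GRCh38.p13, per the submitters' processing notes. The version of STAR, the annotation release, the counter and its settings are not given in the sources used here. Each sample file has 3 count columns. The series table equals the first of these, which counts both strands together, while another column holds most reads and the remaining one held about 5% of the reads of both strands. The main counts therefore ignore strand, so reads from a gene and an antisense or overlapping partner, such as ZNF503-AS1, ZNF503-AS2, ADAMTSL4 and MT-ND6, cannot be told apart, and counts of the column with most reads were an alternative. Near-identical genes (HSPA1A and HSPA1B, HSPA6 and HSPA7, the MT1 genes, histone genes) are uncertain, because it is not given how reads that fit several genes were treated. Symbols and coordinates come from GENCODE 29 on GRCh38, in which 58216 of the 58336 gene IDs were found, and a gene's counts cover its exons.

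Total counts per library ran from 25478614 to 37148046. A gene at 5 CPM thus had over 100 reads in every library, and the median biological coefficient of variation over genes was 3.94%. For a gene without counts in a group, a fold was computed against a floor of 3 counts over the group, and for a gene with 1 to 3 counts the ratio is given with a 95% counting interval. Libraries of a group were compared with a chi-square test of their counts, and all pairs differed by more than sampling noise, with a chi-square per degree of freedom of 1.61 to 5.04, so none was counted as a copy of another. Replicate 3 of zinc-treated wild type stood apart from replicates 1 and 2 of its group, with 4.96 and 5.04, where replicates 1 and 2 had 1.88.

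Genes passing edgeR's filterByExpr (minimum count 10) were tested, 19393 in all, with TMM normalization and edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) on a model of the 6 groups fitted to all 18 libraries. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The 7 main comparisons were zinc and cadmium against water in each genotype, knockout against wild type in water, and the differences of the zinc and of the cadmium response between genotypes, tested as interaction contrasts. The 3 secondary comparisons were cadmium against zinc in wild type and knockout against wild type in zinc and in cadmium. Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. On simulated counts with 50 genes changed at each size among 17798, the test recovered 74, 92, 100 and 100% of changes of 1.25, 1.5, 2 and 4-fold for zinc in wild type, with 7 unchanged genes called. For the difference of the zinc response it recovered 60, 84, 98 and 100%, with 15 unchanged genes called.

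The 21 gene lists were fixed before the data were examined: metallothioneins, zinc transporters, heat shock response, NRF2 targets, ATF4 targets of the integrated stress response, genes of the unfolded protein response of the endoplasmic reticulum (chaperones and others), YAP/TAZ targets, Hippo pathway components, immediate early genes, p53 targets, NF-kB targets, proteasome subunits, cholesterol synthesis, hypoxia response, DNA replication, mitosis, mitochondrially encoded mRNAs, replication-dependent histones, and markers of fibroblasts, of keratinocytes and epithelium, and of blood cells. Of their 413 members 383 were tested. Lists overlap in part, such as in GADD45A (ATF4 and YAP/TAZ targets) and ATF3 (ATF4 targets and immediate early genes). Camera, which compares the genes of a list with all other genes, was run on voom values with a preset correlation of 0.01, adjusted over the 21 lists of a comparison, with an estimated correlation and fry as alternatives.

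The genes named in the text were chosen by a rule also fixed before the data were examined. For each main comparison, eligible genes had an adjusted p under 0.05, a gene symbol that is not a clone name, a mean of at least 5 CPM over the compared libraries and, between a pair of groups, no overlap between the groups, which chance gives for 10% of genes at 3 against 3. The rule took the 5 highest and the 5 lowest log2 fold changes, up to 4 members of each list called by camera and 1 of each other list. A panel of 21 genes was reported whether or not they passed: LATS1, LATS2, MTF1, MT1E, MT1F, MT1G, MT1M, MT1X, MT2A, SLC30A1, HMOX1, HSPA1A, HSPA1B, DDIT3, ATF3, CCN1, CCN2, ANKRD1, AMOTL2, YAP1 and WWTR1. Genes named outside this rule are marked as such.

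The alternatives were RLE normalization, library size alone as scaling, no filter on low counts, a filter of at least 5 CPM in 3 libraries, DESeq2's Wald test, the replicate number as a block, fits to only the groups of a comparison, a threshold of 2-fold, counts of the reverse strand, and leaving out each library in turn. Those of the zinc and cadmium correlation came after the data were seen. The replicate numbers carry no stated meaning in the labels. Residuals of same-numbered libraries correlated by more than 0.1 in all 3 pairs of zinc with cadmium in wild type (0.156, 0.165 and 0.152) and of cadmium between the genotypes (0.329, 0.112 and 0.165), and not in all 3 pairs of the groups of the other comparisons. The blocked values of these comparisons are given where they changed a call. Other splits of the libraries were tested with all 10 splits of each pair of groups and 40 exchanges of genotype labels for each difference of responses.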

Results

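HEK293A cells, an adherent line derived from human embryonic kidney, were compared with cells of the same line labelled as knockouts of both LATS1 and LATS2. LATS1 and LATS2 are the kinases of the Hippo pathway that phosphorylate the transcriptional coactivators YAP and TAZ. Polyadenylated RNA was sequenced from 3 replicates of 6 groups, each genotype after 4 h in water, 250 uM ZnCl2 or 50 uM CdCl2. Levels are counts scaled to library size (CPM), mean ± SD over a group's 3 libraries (n = 3). Changes are edgeR's log2 fold changes ± an approximate standard error from the test statistic, rough at low counts.

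LATS1 (ENSG00000131023, chromosome 6, 149658153 to 149718256) was lower in the libraries labelled knockout than in those labelled wild type under every treatment, with no overlap. The 3 wild-type libraries lay at 77.3 to 82.0 CPM in water, 78.2 to 84.5 CPM in zinc and 92.5 to 97.3 CPM in cadmium. The 3 knockout libraries lay at 44.0 to 46.1, 48.4 to 50.4 and 51.0 to 54.5 CPM. LATS2 (ENSG00000150457, chromosome 13, 20973032 to 21061547) was not lower in the knockout in water, at 18.2 to 18.9 CPM against 16.2 to 16.5 CPM. In zinc it lay at 47.8 ± 3.10 CPM in wild type and 38.2 ± 2.19 CPM in knockout, and in cadmium at 39.0 to 44.7 and 23.8 to 25.7 CPM. The labels give no position of the edits, and an edited gene can still be transcribed, so the LATS2 level does not check the labels. Among the 18 libraries the first principal component, 54.3% of the variance, separated the genotypes, and the next, 21.57%, separated water from both metals.

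**Figure D1:**
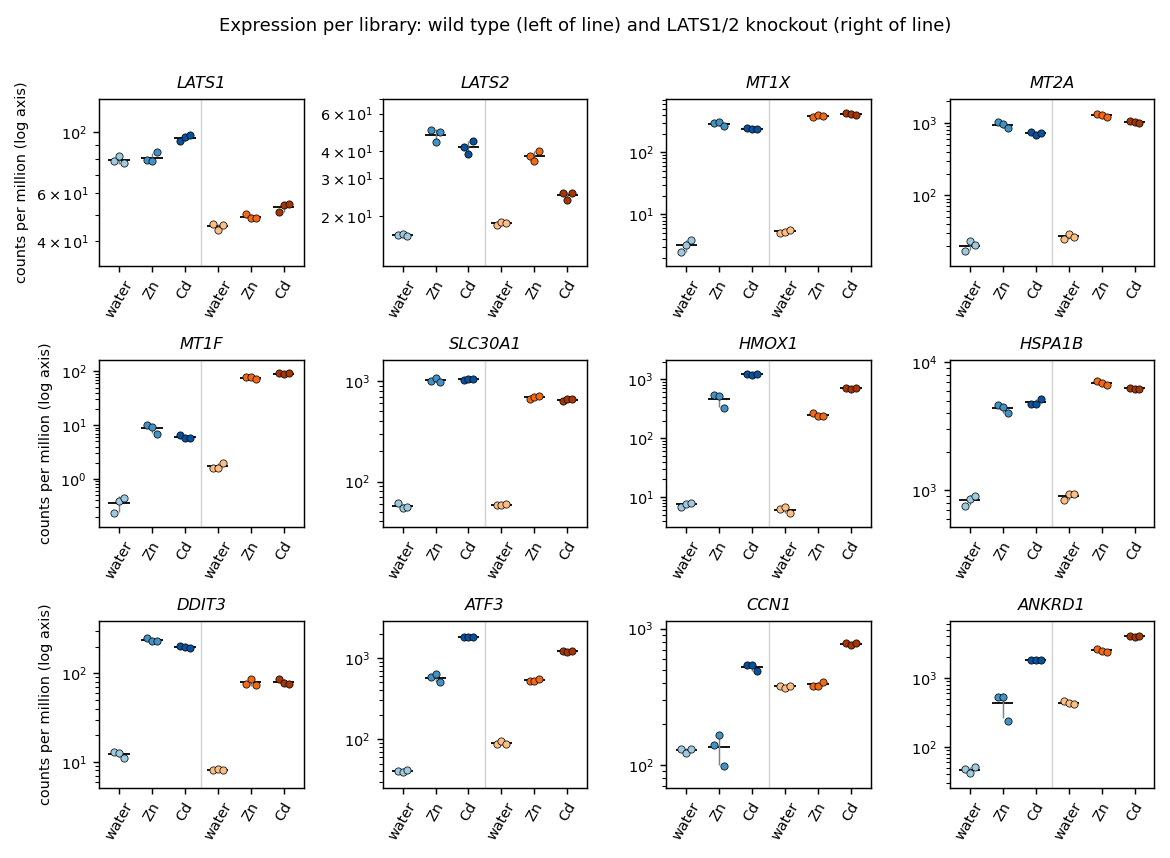
Level of 12 genes in each library (points, CPM on a log axis), with the group mean (horizontal line) and ±SD (vertical line, n = 3), wild type to the left and knockout to the right. LATS1 sat between 77.3 and 97.3 CPM in the 9 wild-type libraries and between 44.0 and 54.5 CPM in the 9 knockout libraries.

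**Figure D2:**
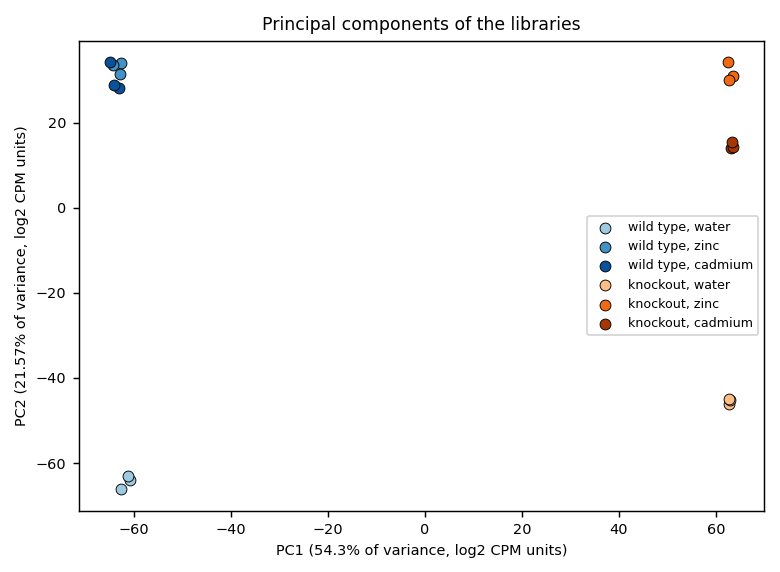
Position of the 18 libraries on the first and next principal component of log CPM, which held 54.3% and 21.57% of the variance, with a colour for each of the 6 groups. The genotypes separated along the first axis and water from both metals along the other, and within a genotype zinc and cadmium lay closer together.

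Zinc treatment of wild-type cells asked which transcripts respond to a load of an essential metal within 4 h. Heat shock, oxidative stress and immediate early mRNAs rose together. Of the metallothioneins 5 of 6 rose, a list that did not pass with an estimated correlation (camera, adjusted p = 0.105). MT1X (ENSG00000187193, chromosome 16, 56682424 to 56684196), which encodes a small cysteine-rich protein that binds metal ions, rose from 3.21 ± 0.676 to 288 ± 20.6 CPM, a log2 fold change of 6.46 ± 0.07. SLC30A1 (ENSG00000170385, chromosome 1, 211571568 to 211578742), the zinc exporter of the plasma membrane, rose from 57.0 ± 3.27 to 1020 ± 47.9 CPM (4.17 ± 0.04). The immediate early transcription factors EGR1 and FOS rose from 7.73 ± 0.634 to 936 ± 15.1 CPM and from 1.20 ± 0.0180 to 142 ± 2.46 CPM, while MYC, a transcription factor that promotes growth, fell from 66.5 ± 3.14 to 4.26 ± 0.436 CPM.

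In all, 11872 of 19393 tested genes changed at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 5678 higher and 6194 lower (4894 and 7167 with library size alone). Of these, 1775 were higher and 922 lower by at least 2-fold. The 5 genes with the highest log2 fold changes among those above 5 CPM were EGR1 (6.92 ± 0.10), FOS (6.88 ± 0.08), the inducible chaperone HSPA6 (6.71 ± 0.27), MT1X and ELAPOR1 (6.34 ± 0.20), of which ELAPOR1 reached 11.8 ± 1.12 CPM from 0.141 ± 0.0250 CPM. The 5 lowest were MYC (-3.96 ± 0.07), the mitochondrial aldehyde dehydrogenase ALDH1B1 (-2.89 ± 0.05), the RNA lariat debranching enzyme DBR1 (-2.61 ± 0.07), the transcription factor DMRT3 (-2.46 ± 0.07) and the lipid droplet protein HILPDA (-2.42 ± 0.11). Their adjusted p ran from 3.02e-48 for FOS to 4.10e-11 for HSPA6 in the edgeR quasi-likelihood test.

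Of the 27 heat shock genes tested, all 27 rose (camera, Benjamini-Hochberg adjusted p = 1.46e-25). The chaperone cofactors DNAJB1 and BAG3 rose by 4.76 ± 0.07 and 3.40 ± 0.06 on the log2 scale, and DNAJB1 reached 4610 ± 396 CPM. Of the 26 immediate early genes, 24 rose, 1, MYC, fell and 1 did not pass (camera, Benjamini-Hochberg adjusted p = 4.50e-17), with MAFF at 6.16 ± 0.08. Of the 27 genes of the integrated stress response, which is driven by the transcription factor ATF4, 25 rose and 2 fell (camera, Benjamini-Hochberg adjusted p = 5.63e-19). Among them were the glutathione-degrading enzyme CHAC1 (4.85 ± 0.09), the transcription factor DDIT3 (4.31 ± 0.07), which rose from 12.2 ± 0.861 to 239 ± 12.6 CPM, and ATF3 (3.81 ± 0.07). ATF3 also stands in the immediate early list. Of the 27 targets of NRF2, the regulator of antioxidant genes, 19 rose and 1 fell (camera, Benjamini-Hochberg adjusted p = 5.24e-08). The heme-degrading enzyme HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214) rose from 7.56 ± 0.676 to 464 ± 120 CPM and the cystine transporter SLC7A11 by 3.16 ± 0.09. Of 13 replication-dependent histone genes, 11 rose and 0 fell (camera, Benjamini-Hochberg adjusted p = 5.77e-05), among them H4C8 (3.96 ± 0.12) and H2BC21 (3.13 ± 0.11), whose sequences resemble those of other histone genes.

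The metallothionein list had 5 of 6 tested members higher and 0 lower, or 6 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 4.01e-04 with the preset correlation, adjusted p = 0.105 with an estimated correlation). MT2A rose from 20.1 ± 2.92 to 950 ± 94.6 CPM and MT1F from 0.360 ± 0.116 to 8.69 ± 1.58 CPM. MT1G had 2 counts in the water libraries together and 27 in the zinc libraries, a ratio of 13.2 with a 95% counting interval of 3.32 to 115, and MT1E and MT1M were not tested, with at most 6 and 1 counts in any group. The MT1 genes resemble each other closely, so the split of reads among them is uncertain. Of the 20 endoplasmic reticulum chaperone genes 13 rose and 5 fell (camera, Benjamini-Hochberg adjusted p = 3.01e-04 with the preset correlation, adjusted p = 0.422 with an estimated correlation), with HERPUD1 at 2.87 ± 0.07 and DNAJB9 at 2.48 ± 0.13. Of 19 mitosis genes 4 rose and 13 fell (camera, Benjamini-Hochberg adjusted p = 0.00332 with the preset correlation, adjusted p = 0.319 with an estimated correlation), among them the kinase PLK1 (-1.03 ± 0.04). Proteasome subunits (16 rose and 4 fell of 31) and mitochondrially encoded mRNAs (7 rose and 1 fell of 13) passed at adjusted p = 0.0117 and 0.0338 in camera, with adjusted p = 0.601 and 0.612 with an estimated correlation. With library size alone as scaling, their adjusted p in camera was 0.195 and 0.209, and without wild-type zinc replicate 1 that of the mitochondrial list was 0.0972.

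The other 11 lists did not pass in camera. Of zinc transporter genes 6 rose and 7 fell of 22, with the vesicular transporter SLC30A2 rising from 0.280 ± 0.391 to 22.5 ± 3.67 CPM. Of YAP/TAZ targets 8 rose and 4 fell of 21, and these members went apart: ANKRD1 rose by 3.20 ± 0.25, CCN2 fell by 0.80 ± 0.11, and CCN1 stood at 128 ± 4.90 and 135 ± 34.2 CPM in water and zinc (adjusted p = 0.684 in the edgeR quasi-likelihood test). Hippo pathway components had 6 higher and 7 lower of 20, p53 targets 7 and 13 of 22, NF-kB targets 6 and 2 of 14, cholesterol synthesis 8 and 8 of 21, the hypoxia response 7 and 6 of 15 and DNA replication 7 and 14 of 23. Markers of fibroblasts had 1 higher and 2 lower of 6, those of keratinocytes and epithelium 1 and 1 of 6, and those of blood cells 2 and 0 of 4. Adjusted over the list alone, the counts differed for metallothioneins as given, for immediate early genes (2 lower) and for p53 targets (9 higher), and were the same for the other 18 lists. Median, mean and test differed in sign for zinc transporters, Hippo components, p53 targets and the hypoxia response, none of which passed. Replicate 3 of zinc-treated wild type stood apart from replicates 1 and 2 in genes of the NRF2 and YAP/TAZ lists: HMOX1 lay at 326 CPM against 541 and 524, ANKRD1 at 235 against 524 and 534, and CCN1 at 98.3 against 139 and 166. Without that library 11511 genes changed.

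Cadmium treatment of wild-type cells asked the same of a toxic metal with no known role in human cells. The heat shock, oxidative stress and immediate early groups rose as well, and so did targets of YAP and TAZ. Of the metallothioneins 5 of 6 rose, again not passing as a list with an estimated correlation (camera, adjusted p = 0.0921). HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910) rose to 1160 ± 96.3 CPM (8.78 ± 0.26) and HMOX1 from 7.56 ± 0.676 to 1220 ± 30.6 CPM (7.32 ± 0.21). MT1X reached 240 ± 4.46 CPM (6.19 ± 0.07) and SLC30A1 1040 ± 20.8 CPM (4.19 ± 0.04). ANKRD1 (ENSG00000148677, chromosome 10, 90912096 to 90921276), a target of YAP and TAZ, rose from 46.7 ± 4.37 to 1820 ± 22.9 CPM (5.28 ± 0.27).

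The edgeR quasi-likelihood test called 11970 genes after Benjamini-Hochberg adjustment, 5822 higher and 6148 lower, with 1864 and 859 at 2-fold or more. The 5 highest were HSPA6, the immediate early transcription factor FOSB (7.99 ± 0.16, from 1.37 ± 0.253 to 342 ± 15.8 CPM), HMOX1, EGR1 (6.62 ± 0.10) and FOS (6.61 ± 0.08). HSPA6 and its near copy HSPA7 share sequence, so reads between them are uncertain. The 5 lowest were MAGEE1 (-3.22 ± 0.13), the microRNA host gene MIR34AHG (-3.15 ± 0.10), the transcription factor SOX2 (-2.61 ± 0.08), and HPS6 (-2.56 ± 0.07) and VPS18 (-2.45 ± 0.07), which act in the transport of lysosomes and related organelles. Adjusted p of these 10 ran from 6.95e-47 for FOS to 1.20e-12 for HSPA6 (edgeR quasi-likelihood test, Benjamini-Hochberg).

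All 27 of 27 heat shock genes rose (camera, Benjamini-Hochberg adjusted p = 3.79e-24), with DNAJB1 at 5170 ± 277 CPM (4.93 ± 0.07). Of 26 immediate early genes 24 rose and 1 fell (camera, Benjamini-Hochberg adjusted p = 1.34e-18). ATF4 targets had 24 higher and 1 lower of 27 (camera, Benjamini-Hochberg adjusted p = 2.37e-19), with ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777) rising from 40.8 ± 0.782 to 1810 ± 11.7 CPM and CHAC1 by 4.86 ± 0.09. NRF2 targets had 18 higher and 3 lower of 27 (camera, Benjamini-Hochberg adjusted p = 7.88e-06), with SLC7A11 at 2.88 ± 0.09 and the thioredoxin reductase TXNRD1 at 1.69 ± 0.06. YAP/TAZ targets had 13 higher and 3 lower of 21 (camera, Benjamini-Hochberg adjusted p = 9.42e-04). Besides ANKRD1, the matricellular protein CCN1 rose from 128 ± 4.90 to 520 ± 29.3 CPM, F3, which encodes tissue factor, by 1.68 ± 0.11, and GADD45A, which the ATF4 list also holds, by 2.56 ± 0.12.

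Metallothioneins had 5 of 6 higher and 0 lower (camera, Benjamini-Hochberg adjusted p = 6.32e-04 with the preset correlation, adjusted p = 0.0921 with an estimated correlation), with MT2A at 729 ± 35.8 CPM and MT1F at 6.09 ± 0.453 CPM. MT1G had 16 counts in cadmium against 2 in water, a ratio of 7.22 with a 95% counting interval of 1.70 to 64.7. Of 31 proteasome subunits 22 rose and 1 fell (camera, Benjamini-Hochberg adjusted p = 1.56e-05 with the preset correlation, adjusted p = 0.303 with an estimated correlation), among them PSMD12 (0.78 ± 0.03). Of 13 mitochondrially encoded mRNAs 11 rose and 0 fell (camera, Benjamini-Hochberg adjusted p = 7.88e-06 with the preset correlation, adjusted p = 0.247 with an estimated correlation), with MT-CO1 at 0.47 ± 0.03. Mitochondrially encoded genes took 5.55 to 5.69% of all counts in the 3 cadmium libraries and 4.75 to 4.90% in the 3 water libraries. Histone genes had 10 higher and 0 lower of 13 (camera, Benjamini-Hochberg adjusted p = 0.00289 with the preset correlation, adjusted p = 0.0869 with an estimated correlation), with H4C8 at 3.71 ± 0.13. Mitosis genes had 4 higher and 12 lower of 19 (camera, Benjamini-Hochberg adjusted p = 0.00844 with the preset correlation, adjusted p = 0.303 with an estimated correlation), with KIF20A at -0.52 ± 0.03, and their adjusted p in camera was 0.0729 among genes with at least 5 CPM in 3 libraries.

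Among the 11 lists that did not pass, unfolded protein response genes had 9 members higher and 9 lower of 20, zinc transporters 7 and 5 of 22, and markers of fibroblasts, of keratinocytes and epithelium and of blood cells 1, 3 and 2 higher and 2, 2 and 0 lower. Counts adjusted over the list alone were larger by a single gene for NRF2 targets, ATF4 targets, unfolded protein response genes and the hypoxia response (higher) and for DNA replication (lower). Median, mean and test did not share a sign for p53 targets, cholesterol synthesis, the hypoxia response and fibroblast markers. With library size alone as scaling, the median of all genes moved to -0.13 and the share of higher genes among those called from 48.6 to 35.5%.

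The same treatment of LATS1/2 knockout cells gave the zinc response in the libraries labelled knockout. Metallothionein, heat shock and immediate early mRNAs rose here too. HSPA6 rose from 1.78 ± 0.423 to 1330 ± 113 CPM (9.56 ± 0.27) and HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946), an inducible chaperone, from 1.87 ± 0.122 to 171 ± 19.2 CPM (6.51 ± 0.11). MT1X rose to 381 ± 8.66 CPM (6.15 ± 0.07) and SLC30A2 from 1.70 ± 0.0529 to 167 ± 3.08 CPM (6.62 ± 0.16). DEPP1 (ENSG00000165507, chromosome 10, 44970981 to 44978810), a regulator of autophagy, fell from 143 ± 1.76 to 3.13 ± 0.277 CPM (-5.51 ± 0.07).

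A total of 10829 genes changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 5456 higher and 5373 lower, with 1392 and 545 at 2-fold or more. Besides HSPA6, SLC30A2, HSPA1A and MT1X, HSPA7 was among the 5 highest, with 962 counts in zinc against 2 in water over 3 libraries each, a ratio of 478 with a 95% counting interval of 132 to 3950. After DEPP1, the lowest were the protocadherin PCDH9 (-2.35 ± 0.06), SHISA2 (-2.26 ± 0.12), the mitochondrial RNA methyltransferase MRM1 (-2.19 ± 0.12) and RTN4RL1 (-2.02 ± 0.13). The share of higher genes among those called moved from 50.4 to 37.2% with library size alone as scaling.

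All 27 of 27 heat shock genes rose (camera, Benjamini-Hochberg adjusted p = 1.64e-32), and DNAJB1 reached 6400 ± 159 CPM. Immediate early genes had 25 higher and 1 lower of 26 (camera, Benjamini-Hochberg adjusted p = 6.18e-22), with EGR1 at 368 ± 35.3 CPM (5.93 ± 0.11) and EGR3 at 5.38 ± 0.12. NRF2 targets had 22 higher and 0 lower of 27 (camera, Benjamini-Hochberg adjusted p = 3.41e-10), with HMOX1 at 246 ± 14.9 CPM (5.33 ± 0.22) and the glutathione synthesis enzyme GCLM at 2.03 ± 0.07. Unfolded protein response genes had 19 higher and 0 lower of 20 (camera, Benjamini-Hochberg adjusted p = 1.34e-13), with HERPUD1 at 2.85 ± 0.07 and HSPA5, the chaperone also called BiP, at 1.24 ± 0.09. ATF4 targets had 17 higher and 3 lower of 27 (camera, Benjamini-Hochberg adjusted p = 1.86e-07). DDIT3 rose to 79.2 ± 6.41 CPM (3.28 ± 0.08), CHAC1 by 3.10 ± 0.11 and the phosphatase subunit PPP1R15A by 3.61 ± 0.04.

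All 6 tested metallothioneins rose (camera, Benjamini-Hochberg adjusted p = 1.90e-07). MT2A reached 1290 ± 52.5 CPM, MT1F rose from 1.74 ± 0.233 to 76.3 ± 4.08 CPM, and MT1G had 773 counts against 2 in water, a ratio of 384 with a 95% counting interval of 106 to 3180. Mitosis genes had 2 higher and 15 lower of 19 (camera, Benjamini-Hochberg adjusted p = 9.70e-07), with PLK1 at -0.76 ± 0.04 and KIF11 at -0.64 ± 0.03. Histone genes had 10 higher and 0 lower of 13 (camera, Benjamini-Hochberg adjusted p = 0.00110), with H2BC12 at 1.11 ± 0.08. Proteasome subunits had 22 higher and 2 lower of 31 (camera, Benjamini-Hochberg adjusted p = 4.28e-04 with the preset correlation, adjusted p = 0.333 with an estimated correlation). The hypoxia response had 9 higher and 3 lower of 15 (camera, Benjamini-Hochberg adjusted p = 0.0242 with the preset correlation, adjusted p = 0.333 with an estimated correlation), with the vasodilator peptide ADM at 1.28 ± 0.05 and VEGFA at 0.76 ± 0.04. Camera's adjusted p for proteasome and hypoxia was 0.0843 and 0.0880 with library size alone, and that of hypoxia was 0.0599 among genes with at least 5 CPM in 3 libraries.

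YAP/TAZ targets did not pass, with 9 higher and 7 lower of 21, and ANKRD1 rose from 431 ± 21.7 to 2490 ± 107 CPM (2.53 ± 0.22). The same held for mitochondrially encoded mRNAs, with 5 higher and 0 lower of 13, and 0 higher and 2 lower with library size alone as scaling. Markers of fibroblasts, of keratinocytes and epithelium and of blood cells had 1, 3 and 3 members higher and 2, 0 and 0 lower, and did not pass. Adjusted over the list alone, a further gene was called for NRF2 targets, unfolded protein response genes, proteasome, hypoxia, DNA replication and keratinocyte and epithelial markers (higher) and for NF-kB targets (lower). Zinc transporters had a median, mean and test that differed in sign.

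Cadmium in the knockout cells gave the corresponding response to the toxic metal. HSPA6 reached 2070 ± 83.0 CPM from 1.78 ± 0.423 CPM (10.20 ± 0.27) and HMOX1 709 ± 18.7 CPM from 6.15 ± 0.678 CPM (6.86 ± 0.21). MT1X rose to 414 ± 12.5 CPM (6.27 ± 0.07) and MT1F to 90.9 ± 1.80 CPM (5.68 ± 0.09). EGR1 rose to 85.2 ± 7.48 CPM (3.82 ± 0.12) and FOSB to 12.9 ± 0.701 CPM. DEPP1 fell to 5.75 ± 0.629 CPM (-4.63 ± 0.06).

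In this comparison 9102 genes changed in the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment, 4492 higher and 4610 lower, with 946 and 311 at 2-fold or more. HSPA7 was among the 5 highest, with 1490 counts against 2, a ratio of 759 with a 95% counting interval of 210 to 6280. Besides DEPP1, the 5 lowest held the growth arrest gene GAS1 (-2.30 ± 0.10), the iron exporter SLC40A1 (-2.21 ± 0.14), PCDH9 (-2.20 ± 0.06) and MIR34AHG (-2.20 ± 0.10). With library size alone as scaling the median of all genes moved to -0.12 and the share of higher genes among those called from 49.4 to 28.8%.

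All 27 of 27 heat shock genes (camera, Benjamini-Hochberg adjusted p = 3.28e-41) and all 6 tested metallothioneins (camera, Benjamini-Hochberg adjusted p = 2.91e-10) rose. HSPA1A reached 90.9 ± 1.03 CPM (5.60 ± 0.12), MT2A 1040 ± 30.7 CPM, and MT1G had 881 counts against 2, a ratio of 449 with a 95% counting interval of 124 to 3710. ATF4 targets had 26 higher and 0 lower of 27 (camera, Benjamini-Hochberg adjusted p = 7.24e-31), with CHAC1 rising by 5.20 ± 0.09. NRF2 targets had 20 higher and 1 lower of 27 (camera, Benjamini-Hochberg adjusted p = 2.77e-11). Immediate early genes had 21 higher and 2 lower of 26 (camera, Benjamini-Hochberg adjusted p = 8.23e-19), with the phosphatase DUSP1 at 3.93 ± 0.15.

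YAP/TAZ targets had 11 higher and 6 lower of 21 (camera, Benjamini-Hochberg adjusted p = 0.0105 with the preset correlation, adjusted p = 0.0822 with an estimated correlation), with ANKRD1 reaching 4030 ± 59.1 CPM (3.23 ± 0.23), CCN1 rising by 1.05 ± 0.12 and CCN2 at 397 ± 16.5 and 403 ± 6.66 CPM in water and cadmium. Proteasome subunits had 22 higher and 0 lower of 31 (camera, Benjamini-Hochberg adjusted p = 9.19e-06 with the preset correlation, adjusted p = 0.321 with an estimated correlation). The hypoxia response had 9 higher and 4 lower of 15 (camera, Benjamini-Hochberg adjusted p = 0.0130 with the preset correlation, adjusted p = 0.321 with an estimated correlation), with VEGFA at 1.22 ± 0.04. Mitosis genes had 2 higher and 10 lower of 19, or 13 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 8.49e-04 with the preset correlation, adjusted p = 0.218 with an estimated correlation). Unfolded protein response genes had 10 higher and 3 lower of 20 (camera, Benjamini-Hochberg adjusted p = 8.70e-04 with the preset correlation, adjusted p = 0.321 with an estimated correlation), and 8 higher and 9 lower with library size alone as scaling. Mitochondrially encoded mRNAs had 7 higher and 0 lower of 13 (camera, Benjamini-Hochberg adjusted p = 0.0307 with the preset correlation, adjusted p = 0.530 with an estimated correlation), and 1 higher and 4 lower with library size alone.

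The camera call of the mitochondrial list was lost with library size alone (adjusted p = 0.823), without knockout cadmium replicate 1 (0.144) and without knockout water replicate 3 (0.207). Those of proteasome and hypoxia were lost with library size alone (0.0805 and 0.0743), and that of hypoxia also among genes with at least 5 CPM in 3 libraries (0.0580). The other 10 lists did not pass, among them histones with 7 higher and 0 lower and blood cell markers with 1 higher, or 0 adjusted over the list alone. Zinc transporters, cholesterol synthesis and DNA replication had a median, mean and test of unlike sign.

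**Figure D3:**
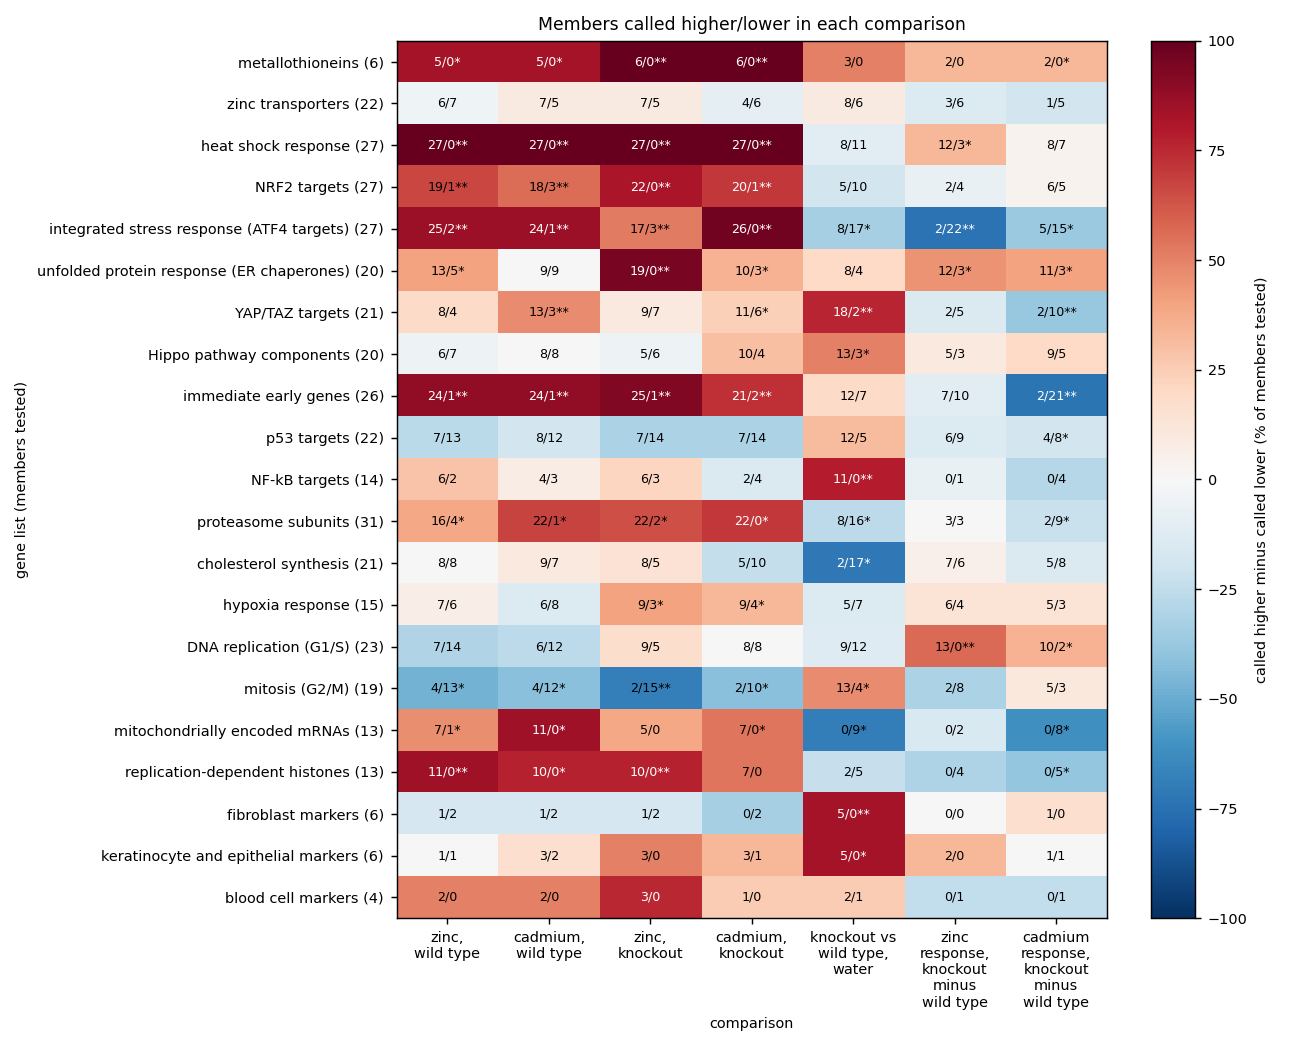
Heatmap of 21 gene lists against the 7 main comparisons, coloured by genes called higher minus genes called lower as a percentage of the tested members, with the numbers higher/lower written in each cell. An asterisk marks a camera call with the preset correlation and a pair of asterisks a call that also held with an estimated correlation, and all 27 heat shock genes rose in each of the 4 metal comparisons.

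Knockout and wild-type cells in water gave the difference between the genotypes without metal. YAP/TAZ targets were higher in the knockout: ANKRD1 lay at 431 ± 21.7 against 46.7 ± 4.37 CPM (3.20 ± 0.25), CCN1 at 376 ± 6.72 against 128 ± 4.90 CPM (1.55 ± 0.13) and CCN2 at 397 ± 16.5 against 183 ± 11.4 CPM (1.12 ± 0.10). The receptor tyrosine kinase AXL was higher by 4.28 ± 0.14. Of the enzymes of cholesterol synthesis 17 of 21 were lower, a list that did not pass with an estimated correlation (camera, adjusted p = 0.0707), with IDI1 at -2.44 ± 0.05 and SQLE at -1.02 ± 0.03. YAP1 itself did not differ by more than the spread (adjusted p = 0.228, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and WWTR1, which encodes TAZ, was lower by -0.46 ± 0.04.

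The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 12170 genes, 5952 higher and 6218 lower in the knockout (6687 and 5418 with library size alone), with 1981 and 875 at 2-fold or more. Among the 5 highest, XAGE2 had 0 counts in wild type and 1595 in the knockout, at least 505-fold against a floor of 3 counts over the 3 libraries. CDH13 had 2 counts in wild type, and its ratio was 983 with a 95% counting interval of 272 to 8120. Intervals and floors cover counting error only. BMP2, a growth factor, lay at 58.2 ± 1.49 against 0.0711 ± 0.0613 CPM, RFX7 at 36.4 ± 0.242 against 0.0586 ± 0.0520 CPM and OLR1 at 54.0 ± 0.426 against 0.0962 ± 0.0641 CPM. The 5 lowest were ZNF503-AS1 (-6.16 ± 0.17), ZNF503-AS2 (-4.44 ± 0.09), COL14A1 (-4.44 ± 0.06), EPHA3 (-3.96 ± 0.07) and CAMK2B (-3.79 ± 0.14). These counts ignored strand, and with counts of the reverse strand alone both ZNF503 antisense genes were lower too and passed. Genotype and line cannot be told apart.

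YAP/TAZ targets had 18 members higher and 2 lower of 21 (camera, Benjamini-Hochberg adjusted p = 6.55e-08), with MYOF at 3.64 ± 0.10 and IGFBP3 at 2.61 ± 0.10. NF-kB targets had 11 higher and 0 lower of 14 (camera, Benjamini-Hochberg adjusted p = 0.00193), with NFKB2 at 1.02 ± 0.07 and its inhibitor gene NFKBIA at 0.60 ± 0.06. Fibroblast markers had 5 higher and 0 lower of 6, or 6 higher adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 6.24e-04), with the collagens COL5A1 (3.90 ± 0.05) and COL1A1, which lay at 31.8 ± 3.11 against 7.19 ± 1.07 CPM. Keratinocyte and epithelial markers had 5 higher and 0 lower of 6 (camera, Benjamini-Hochberg adjusted p = 0.00114 with the preset correlation, adjusted p = 0.0515 with an estimated correlation), with SFN at 3.75 ± 0.10 and KRT19 at 2.52 ± 0.06. Blood cell markers had 2 higher and 1 lower of 4 and did not pass.

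Hippo pathway components had 13 higher and 3 lower of 20 (camera, Benjamini-Hochberg adjusted p = 0.00214 with the preset correlation, adjusted p = 0.124 with an estimated correlation), among them the scaffold AMOT (1.61 ± 0.05) and the transcription factors TEAD4 (0.81 ± 0.04) and TEAD1 (0.77 ± 0.03). Cholesterol synthesis had 2 higher and 17 lower of 21 (camera, Benjamini-Hochberg adjusted p = 2.57e-06 with the preset correlation, adjusted p = 0.0707 with an estimated correlation). ATF4 targets had 8 higher and 17 lower of 27 (camera, Benjamini-Hochberg adjusted p = 0.00448 with the preset correlation, adjusted p = 0.293 with an estimated correlation), with the amino acid transporter SLC7A5 at -2.09 ± 0.03, its partner SLC3A2 at -1.49 ± 0.03 and, in the other direction, ATF3 at 1.14 ± 0.08. Mitosis genes had 13 higher and 4 lower of 19 (camera, Benjamini-Hochberg adjusted p = 0.00406 with the preset correlation, adjusted p = 0.293 with an estimated correlation), with UBE2C at 0.86 ± 0.04. Mitochondrially encoded mRNAs had 0 higher and 9 lower of 13 (camera, Benjamini-Hochberg adjusted p = 0.00214 with the preset correlation, adjusted p = 0.511 with an estimated correlation), and proteasome subunits 8 and 16 of 31 (camera, Benjamini-Hochberg adjusted p = 0.0434 with the preset correlation, adjusted p = 0.694 with an estimated correlation). The proteasome call was lost in 5 alternatives, with adjusted p up to 0.219, among them those without knockout water replicate 3 (0.0694) and without wild-type water replicate 1 (0.0717). The calls of NF-kB and ATF4 targets were lost among genes with at least 5 CPM in 3 libraries (0.0931 and 0.0525).

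Before metal, metallothioneins did not pass as a list (3 of 6 higher), while MT1X, MT2A and MT1F were higher by 0.71 ± 0.13, 0.41 ± 0.12 and 2.24 ± 0.27. Heat shock genes had 8 higher and 11 lower of 27, with a median, mean and test of unlike sign. NRF2 targets had 5 higher and 10 lower, unfolded protein response genes 8 and 4, immediate early genes 12 and 7, p53 targets 12 and 5, zinc transporters 8 and 6, hypoxia 5 and 7, DNA replication 9 and 12 and histones 2 and 5. None of these passed in camera. Adjusted over the list alone, Hippo components had 4 lower and immediate early genes 13 higher.

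RFX7, a transcription factor gene among the 5 highest, lies on chromosome 15 (56087280 to 56243266) next to genes that showed the same pattern. Between 55826922 and 56465137, NEDD4, RFX7, TEX9 and MNS1 lay at 22.5, 36.4, 5.53 and 5.96 CPM in the knockout and at 0.052, 0.059, 0.009 and 0.009 CPM in wild type. Of their neighbours, PRTG lay at 31.1 against 1.18 CPM, PYGO1 at 29.8 against 28.5 CPM, ZNF280D at 2.15 against 4.47 CPM and TCF12 at 58.2 against 48.8 CPM. Apart from RFX7, these genes were chosen after their values were seen.

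**Figure D4:**
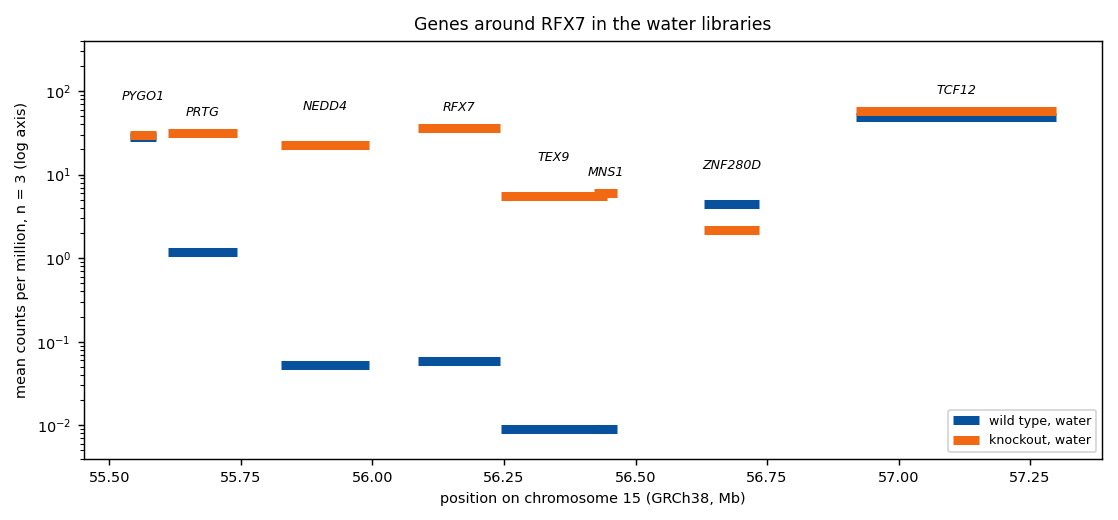
Mean level in water (CPM, log axis) of wild type and knockout for genes drawn from start to end on chromosome 15 (GRCh38, Mb). NEDD4, RFX7, TEX9 and MNS1 lay at 5.53 to 36.4 CPM in the knockout and at 0.009 to 0.059 CPM in wild type.

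The difference of the zinc response between the genotypes (knockout minus wild type, log2) addressed the part of the response that depended on genotype. The integrated stress response rose less in the knockout: DDIT3 went from 8.12 ± 0.191 to 79.2 ± 6.41 CPM there and from 12.2 ± 0.861 to 239 ± 12.6 CPM in wild type, a difference of -1.02 ± 0.12. TRIB3, an inhibitor of the same pathway, stood at 27.5 ± 1.95 and 30.5 ± 1.31 CPM in knockout water and zinc and at 21.4 ± 0.488 and 141 ± 14.4 CPM in wild type (-2.58 ± 0.10). HSPA1A rose more in the knockout, to 153 to 191 CPM against 13.7 to 16.6 CPM over the 3 libraries (3.36 ± 0.28). The zinc exporter SLC30A1 rose less, to 689 ± 16.6 against 1020 ± 47.9 CPM (-0.62 ± 0.05). The changes of MT1X, MT2A, MTF1 and HMOX1 did not differ by more than the spread (adjusted p = 0.104, 0.945, 0.949 and 0.31, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

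The difference passed for 4834 genes (edgeR quasi-likelihood test, Benjamini-Hochberg), 2788 more positive and 2046 more negative in the knockout, 189 and 314 of them by at least 2-fold. With library size alone the numbers were 2334 and 2349, and with RLE normalization 2451 and 2261. The 5 highest were HSPA1A, MYC (2.92 ± 0.10), HSPA6 (2.85 ± 0.66), the pseudokinase TRIB1 (2.82 ± 0.18) and the phosphatase DUSP4 (2.23 ± 0.08). MYC fell in both genotypes, from 38.2 ± 0.432 to 18.4 ± 1.43 CPM in the knockout. Without wild-type water replicate 3 the HSPA6 difference was 2.36 and no longer passed (edgeR adjusted p = 0.0683). The 5 lowest were DEPP1 (-3.07 ± 0.23), the mTOR inhibitor DDIT4 (-2.86 ± 0.30), BMP2 (-2.82 ± 0.55), TRIB3 and PCDH9 (-2.39 ± 0.10). The BMP2 value rests on few wild-type reads (0.0711 and 0.258 CPM in water and zinc). Of the counts of the near-identical neighbours HSPA1A and HSPA1B, HSPA1A took 2.43% in knockout zinc and 0.351% in wild-type zinc. HSPA1B differed by 0.56 ± 0.10.

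ATF4 targets had 2 members with a more positive and 22 with a more negative change in the knockout of 27, or 2 and 23 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.09e-27), among them STC2 (-1.98 ± 0.07) and SESN2 (-1.78 ± 0.05). DNA replication genes had 13 more positive and 0 more negative of 23, or 15 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.19e-07), with PCNA at 0.37 ± 0.04 and UHRF1 at 0.35 ± 0.05. Unfolded protein response genes had 12 and 3 of 20, 13 and 4 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 6.78e-04 with the preset correlation, adjusted p = 0.529 with an estimated correlation), with HSPA5 at 0.78 ± 0.13 and SDF2L1 at 0.94 ± 0.09. Heat shock genes had 12 and 3 of 27 (camera, Benjamini-Hochberg adjusted p = 0.00686 with the preset correlation, adjusted p = 0.634 with an estimated correlation), with HSPB1 at 0.92 ± 0.11, and their camera adjusted p was 0.0738 among genes with at least 5 CPM in 3 libraries. Leaving out each library in turn ended none of these 4 list calls.

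Of the 17 lists that did not pass, metallothioneins had 2 more positive and 0 more negative members. MT1F differed by 0.90 ± 0.34 (edgeR adjusted p = 0.0484), a call lost in 10 alternatives with adjusted p up to 0.301, the highest without wild-type water replicate 3. MT1G differed by 4.85 ± 1.67, but that fit rests on 2 counts in the water libraries of each genotype, and the call was lost without wild-type water replicate 1 (edgeR adjusted p = 0.165) or replicate 3 (0.152). YAP/TAZ targets had 2 more positive and 5 more negative of 21, and the differences of CCN1, CCN2 and ANKRD1 did not pass (edgeR adjusted p = 0.962, 0.148 and 0.172). AMOTL2, a YAP/TAZ target whose product restrains YAP, differed by 0.38 ± 0.05. Immediate early genes had 7 and 10, or 9 and 11 adjusted over the list alone, with a median of 0.05 and a mean of -0.04. Signs of median, mean and test differed also for NRF2 targets, Hippo components, cholesterol synthesis and keratinocyte and epithelial markers. Without replicate 3 of zinc-treated wild type, 4720 genes passed.

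For cadmium, the corresponding difference was led by a smaller immediate early response in the knockout. FOSB rose to 12.9 ± 0.701 CPM in the knockout and 342 ± 15.8 CPM in wild type (-4.94 ± 0.46), EGR1 to 85.2 ± 7.48 and 766 ± 26.4 CPM (-2.80 ± 0.20) and FOS to 27.7 ± 0.980 and 117 ± 4.90 CPM (-2.49 ± 0.20). The YAP/TAZ targets ANKRD1 (-2.05 ± 0.33) and CCN1 (-0.97 ± 0.17) also rose less in the knockout, from a higher level in water, and CCN2 differed by -0.60 ± 0.14. SLC30A1 rose less (-0.72 ± 0.05) and HSPA1A more (2.62 ± 0.28). For MT1X, MT2A and HMOX1 the difference did not pass (adjusted p = 0.741, 0.661 and 0.423, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

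It passed for 5488 genes (edgeR quasi-likelihood test, Benjamini-Hochberg), 2742 more positive and 2746 more negative in the knockout, 212 and 471 of them by at least 2-fold. The 5 highest were HSPA1A, MYC (2.27 ± 0.08), IER5 (2.23 ± 0.05), MAGEE1 (1.78 ± 0.17) and the transcription factor HEY1 (1.68 ± 0.09). The 5 lowest were FOSB, the synaptic gene ARC (-3.03 ± 0.13), EGR1, ADAMTSL4 (-2.58 ± 0.15) and FOS. With counts of the reverse strand alone, which hold most reads of these stranded libraries, ADAMTSL4 stood at 0.50 and did not pass (edgeR adjusted p = 0.190), so its value is uncertain.

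Immediate early genes had 2 members more positive and 21 more negative of 26 (camera, Benjamini-Hochberg adjusted p = 1.06e-15). YAP/TAZ targets had 2 and 10 of 21, or 2 and 12 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.28e-04), with F3 at -1.31 ± 0.14 and TGFB2 at -1.06 ± 0.14. ATF4 targets had 5 and 15 of 27, 6 and 16 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 8.12e-05 with the preset correlation, adjusted p = 0.215 with an estimated correlation), with ATF3 at -1.71 ± 0.10 and DDIT3 at -0.72 ± 0.12. Mitochondrially encoded mRNAs had 0 and 8 of 13, 10 more negative adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 4.00e-07 with the preset correlation, adjusted p = 0.245 with an estimated correlation), with MT-CO1 at -0.29 ± 0.04. Unfolded protein response genes had 11 and 3 of 20 (camera, Benjamini-Hochberg adjusted p = 0.00465 with the preset correlation, adjusted p = 0.453 with an estimated correlation), with HSPA5 at 0.64 ± 0.13. Metallothioneins had 2 and 0 of 6 (camera, Benjamini-Hochberg adjusted p = 0.0143 with the preset correlation, adjusted p = 0.245 with an estimated correlation), with MT1F at 1.66 ± 0.36 and MT1G at 5.89 ± 1.75, a fit that rests on 2 counts in the water libraries of each genotype and lost its call without wild-type water replicate 1 (edgeR adjusted p = 0.0862) or 3 (0.0789).

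Histones had 0 more positive and 5 more negative of 13 (camera, Benjamini-Hochberg adjusted p = 0.0161 with the preset correlation, adjusted p = 0.237 with an estimated correlation) and DNA replication 10 and 2 of 23 (camera, Benjamini-Hochberg adjusted p = 0.0169 with the preset correlation, adjusted p = 0.245 with an estimated correlation). Proteasome subunits had 2 and 9 of 31, 4 and 12 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0239 with the preset correlation, adjusted p = 0.602 with an estimated correlation), with PSMD12 at -0.40 ± 0.04. p53 targets had 4 and 8 of 22 (camera, Benjamini-Hochberg adjusted p = 0.0462 with the preset correlation, adjusted p = 0.279 with an estimated correlation), with the p53 regulator MDM2 at -0.66 ± 0.04 and the apoptosis gene BBC3 at -0.90 ± 0.08. Among genes with at least 5 CPM in 3 libraries the camera adjusted p was 0.0716 for metallothioneins and for DNA replication, 0.0607 for histones, 0.0580 for proteasome and 0.0899 for p53 targets. The proteasome call was lost without knockout cadmium replicate 3 (0.0880), knockout water replicate 1 (0.0753), wild-type cadmium replicate 1 (0.0566) or wild-type water replicate 2 (0.0727), and the p53 call without knockout cadmium replicate 3 (0.0706), knockout water replicate 1 (0.0626), wild-type cadmium replicate 1 (0.0934) or wild-type water replicate 3 (0.105).

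Heat shock genes did not pass (8 more positive and 7 more negative of 27, 12 and 7 adjusted over the list alone), nor did NRF2 targets (6 and 5 of 27). NF-kB targets had 0 and 4 of 14, 2 and 5 adjusted over the list alone, and hypoxia 5 and 3, 6 and 3 adjusted over the list alone. Median, mean and test were of unlike sign for NRF2 targets, cholesterol synthesis, fibroblast markers and blood cell markers. MTF1, the transcription factor that senses zinc and drives metallothionein genes, differed by -0.39 ± 0.07, having risen in cadmium from 36.2 ± 1.49 to 51.4 ± 1.42 CPM in wild type and stood at 31.7 ± 2.25 and 34.7 ± 0.587 CPM in the knockout.

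Cadmium against zinc within wild type separated 10161 genes (edgeR quasi-likelihood test, Benjamini-Hochberg), 5301 higher and 4860 lower in cadmium (4425 and 5947 with library size alone), with 833 and 747 at 2-fold or more. HMOX1 (1.40 ± 0.14), ATF3 (1.66 ± 0.06), ANKRD1 (2.08 ± 0.22), CCN1 (1.95 ± 0.13) and FOSB (2.54 ± 0.09) were higher in cadmium. MT1X (-0.27 ± 0.04), MT2A (-0.38 ± 0.07) and SLC30A2 (-2.33 ± 0.17) were higher in zinc. Unfolded protein response genes had 2 members higher and 15 lower in cadmium of 20 (camera, Benjamini-Hochberg adjusted p = 4.83e-06 with the preset correlation, adjusted p = 0.514 with an estimated correlation), with ERN1 at -1.16 ± 0.05. Mitochondrially encoded mRNAs had 10 and 0 of 13 (camera, Benjamini-Hochberg adjusted p = 0.00104 with the preset correlation, adjusted p = 0.823 with an estimated correlation), and histones 0 and 8 of 13 (camera, Benjamini-Hochberg adjusted p = 0.0413 with the preset correlation, adjusted p = 0.514 with an estimated correlation). The histone call was lost with library size alone (0.0527) and without wild-type cadmium replicate 2 (0.0543), and the other 18 lists did not pass. With the replicate number as a block 6 lists passed, the further ones being heat shock genes, lower in cadmium (camera, adjusted p = 0.0420), and YAP/TAZ targets (adjusted p = 0.0378) and proteasome subunits (adjusted p = 0.0420), higher in cadmium. Leaving out 1 library added YAP/TAZ targets in all 6 cases, proteasome subunits in 4, heat shock genes in 2 and metallothioneins in 1.

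Between the genotypes 12894 genes differed in zinc (6579 higher and 6315 lower in the knockout) and 12989 in cadmium (6314 and 6675, or 7045 and 5888 with library size alone) in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. YAP/TAZ targets had 17 higher and 2 lower in zinc (camera, Benjamini-Hochberg adjusted p = 1.24e-06), and 17 and 2 in cadmium (camera, Benjamini-Hochberg adjusted p = 3.49e-05). ATF4 targets had 2 higher and 24 lower in zinc (camera, Benjamini-Hochberg adjusted p = 1.14e-15), with TRIB3 at -2.21 ± 0.06 and ASNS, which makes asparagine, at -2.14 ± 0.07. In cadmium they had 4 higher and 23 lower (camera, Benjamini-Hochberg adjusted p = 4.67e-08 with the preset correlation, adjusted p = 0.0543 with an estimated correlation). All 6 tested metallothioneins were higher in the knockout in zinc (camera, Benjamini-Hochberg adjusted p = 0.00200 with the preset correlation, adjusted p = 0.133 with an estimated correlation) and in cadmium (camera, Benjamini-Hochberg adjusted p = 2.00e-04 with the preset correlation, adjusted p = 0.0557 with an estimated correlation), with MT1F at 3.14 ± 0.07 and 3.90 ± 0.07. Immediate early genes had 16 higher and 6 lower in zinc (camera, Benjamini-Hochberg adjusted p = 0.0442 with the preset correlation, adjusted p = 0.439 with an estimated correlation) and 6 and 19 in cadmium (camera, Benjamini-Hochberg adjusted p = 2.43e-04 with the preset correlation, adjusted p = 0.132 with an estimated correlation). The zinc call of immediate early genes was lost without knockout zinc replicate 2 (0.0526) or wild-type zinc replicate 3 (0.0585).

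The other 9 lists called between the genotypes in both metals lost their call with an estimated correlation, and the values in parentheses are the adjusted p with an estimated correlation in zinc and in cadmium. Mitochondrially encoded mRNAs had 0 members higher in the knockout and 10 lower in zinc and 13 lower in cadmium (adjusted p = 0.306 and 0.132). Cholesterol synthesis had 16 lower in both (adjusted p = 0.0647 and 0.0557). Fibroblast markers had 5 of 6 higher in both (adjusted p = 0.0518 and 0.0543), as did 5 of 6 keratinocyte and epithelial markers (adjusted p = 0.0647 and 0.0557). Mitosis genes had 14 and 15 higher (adjusted p = 0.395 and 0.132), Hippo components 12 and 14 higher (adjusted p = 0.145 and 0.0682), unfolded protein response genes 12 and 10 higher (adjusted p = 0.478 and 0.557), proteasome subunits 17 and 23 lower (adjusted p = 0.582 and 0.363) and histones 8 and 8 lower (adjusted p = 0.137 and 0.134). NF-kB targets passed in zinc alone, 11 higher and 3 lower (adjusted p = 0.0647 with an estimated correlation). Among genes with at least 5 CPM in 3 libraries, the zinc calls of NF-kB targets (0.118), mitosis genes (0.0701), immediate early genes (0.0999) and proteasome subunits (0.0999) were lost, the last also with library size alone (0.0638). Without a library, the call of mitosis genes in zinc was lost without knockout zinc replicate 3 (0.0784) or wild-type zinc replicate 1 (0.0586), and that of unfolded protein response genes in cadmium without wild-type cadmium replicate 3 (0.0501).

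Over the 10 comparisons, the camera calls that held with an estimated correlation were 5 of 10 for zinc and 5 of 10 for cadmium in wild type, 8 of 10 and 5 of 11 in the knockout, 3 of 10 for the genotypes in water, 2 of 4 and 2 of 10 for the differences of the zinc and cadmium responses, 0 of 3 for cadmium against zinc, and 2 of 14 and 1 of 13 for the genotypes in zinc and cadmium. Those named above without an estimated value are the ones that held.

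Across the 19393 genes, the zinc responses of wild type and knockout had a Pearson r of 0.767 and a Spearman rho of 0.745, and the cadmium responses 0.727 and 0.705. These are correlations across genes, which are not independent replicates. Among 11325 genes at 5 CPM or more on average, Pearson's r was 0.873 for zinc and 0.874 for cadmium. In zinc, 4066 genes rose in both genotypes and 4284 fell in both, where independent lists would share 1597 and 1716, and 310 went in opposite directions. In cadmium, 3538 rose and 3788 fell in both, against 1349 and 1461, and 269 went apart. The difference between the genotypes was called for 2657 genes in both metals, 2410 of them in the same direction.

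Among the 11325 genes at 5 CPM or more on average, those with a mean response of at least 2-fold over both genotypes changed less in the knockout. The 318 such genes that went up in cadmium had a median log2 fold change of 1.69 in wild type and 1.28 in the knockout, and 82.4% of them a smaller change in the knockout. Where the difference itself was called, it was smaller in the knockout for 210 of these genes and larger for 27. The 137 that went down had medians of -1.40 and -1.03 (86.1% smaller, with calls for 81 smaller and 6 larger). In zinc, the 362 genes that went up had medians of 1.48 and 1.31 (63.8% smaller, with calls for 135 smaller and 55 larger). The 206 that went down had -1.44 and -1.09 (79.6% smaller, with calls for 124 and 14). The zinc and cadmium responses of wild type, which share their 3 water libraries, had a Pearson r of 0.751, a Spearman rho of 0.655 and a covariance of 0.624. In 20 simulations of unchanged groups against the same controls the mean r was 0.517 and the mean covariance 0.0533, a difference in covariance of 0.571. They shared 3732 higher and 4213 lower genes, against 1705 and 1964 for independent lists and 0 in the simulations, and 1065 genes went apart. Since 3 control libraries do not give 2 parts of at least 2 libraries, the controls were not split, and part of the excess over independent lists can come from them.

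**Figure D5:**
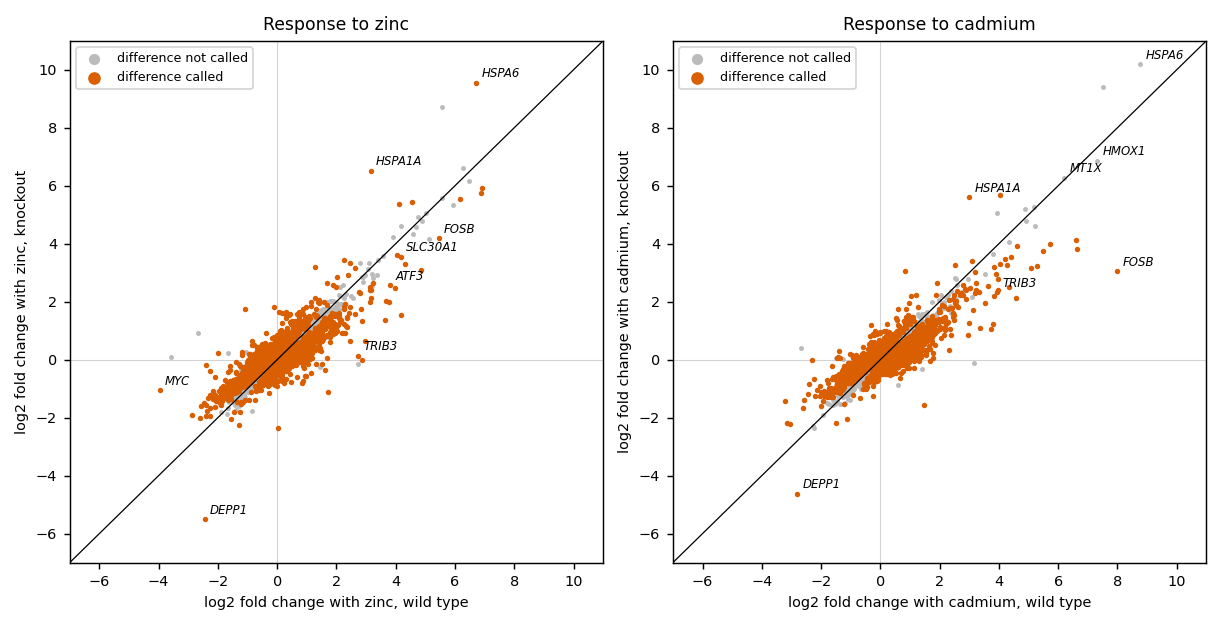
Log2 fold change in wild type (x axis) and knockout (y axis) of the 11325 genes at 5 CPM or more, for zinc and cadmium, with genes whose response differed between the genotypes in orange and the diagonal marking equal responses. Pearson's r across these genes was 0.873 for zinc and 0.874 for cadmium.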

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

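The tests of HSPA1A read shares and of exchanges that move equal numbers of libraries were chosen only after the results were seen, and the other tests here were fixed before.

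The difference of the metal response between the genotypes, tested as an interaction, called 4834 genes and 4 gene lists for zinc and 5488 genes and 10 lists for cadmium. These results drew attention because the genotypes answered the same metal differently. In zinc, the log2 change in the knockout minus that in wild type was -0.51 for LATS2, -0.62 for SLC30A1, -1.02 for DDIT3 and -1.24 for ATF3, and 0.56 for HSPA1B, 0.38 for AMOTL2 and 3.36 for HSPA1A. MT1F (0.90) and WWTR1 (0.17) passed too but lost the call in 10 and 12 alternatives, with adjusted p up to 0.301 without wild-type water replicate 3 and up to 0.146. In cadmium it was -0.92 for LATS2, -0.39 for MTF1, -0.72 for SLC30A1, -0.72 for DDIT3, -1.71 for ATF3, -0.97 for CCN1, -0.60 for CCN2 and -2.05 for ANKRD1, and 1.66 for MT1F and 2.62 for HSPA1A. AMOTL2 (-0.13) and YAP1 (0.15) passed in cadmium, with the call lost in 7 and 2 alternatives and adjusted p up to 0.159 and 0.0719. MT1G, at 4.85 in zinc and 5.89 in cadmium, rests on 2 counts in the water libraries of each genotype.

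Exchanging genotype labels within treatments, 7 of 40 exchanges for zinc and 5 of 40 for cadmium, the real labels included, called as many genes as the real 4834 and 5488, with up to 13967 and 14007 genes in other exchanges. These shares exceed 0.05, so chance was not excluded by this test. All 6 and 4 other exchanges of that size moved unequal numbers of libraries in water and in metal, which puts the genotype difference itself into the contrast. With equal numbers moved, 1 of 40 exchanges, the real one, called as many for zinc and for cadmium, and the highest other called 0. These exchanges mix the genotypes within every relabelled group, which puts the genotype difference into the spread. In each of the 8 comparisons of a pair of groups, 1 of 10 splits, the real one, called as many genes, from 9102 to 12989. The highest other called 1 in water between the genotypes and 0 elsewhere. Other splits mix the groups too, and 10 are too few for a share under 0.05. Few or no calls were thus given beforehand for equal exchanges and splits, and neither decides about chance. The 0 of cadmium against zinc and of the genotypes in cadmium includes the splits that part every same-numbered pair.

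HSPA1A rose more in the knockout than in wild type in both metals, while its near-identical neighbour HSPA1B differed by 0.56 in zinc and did not pass in cadmium. A fixed share of HSPA1B reads assigned to HSPA1A would keep the share of HSPA1A in both genes constant, but in the knockout it was 11.65 times higher in zinc than in water (2.43 against 0.209%). A sequence variant of the knockout line that moves HSPA1B reads to HSPA1A would raise that share in water as well, where it was 1.04 times that of wild type. These values argue against both, and an effect of the genotype on HSPA1A stays open as an untested hypothesis.

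Genes at 5 CPM or more with a mean cadmium response of at least 2-fold changed less in the knockout in both directions. A higher level before treatment in the knockout is a candidate explanation, but among 108 such genes with levels within 0.25 (log2) of each other in water the median difference of response was -0.50. A constant offset from normalization would push all genes one way, but the 137 genes that went down had a median difference of 0.39. These values argue against both as the whole cause. An effect of the genotype stays open as a hypothesis, which these libraries do not separate from other differences between the lines.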

How the results depend on the processing

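The correlation of the zinc and cadmium responses in wild type received its alternatives after the data were seen, and all other alternatives here were planned. Of 9570 values of named genes under an alternative, 9454 kept their direction and side of the threshold, 88 lost the call, 24 gained it and 4 reversed. Of 2762 list results 2534 were the same, 108 weaker (62 of them with an estimated correlation), 117 stronger (67 with fry) and 3 reversed. Of 502 summary results 441 stayed within the set range and 61 moved. Counts of changed genes stayed within 1.5 times in every alternative but the 2-fold threshold, which by its construction left 2697 (zinc, wild type), 2723 (cadmium, wild type), 1937 (zinc, knockout), 1257 (cadmium, knockout), 2856 (genotypes in water), 503 and 683 (differences of the zinc and cadmium responses), 1580 (cadmium against zinc), 3158 and 3204 (genotypes in zinc and cadmium). With library size only, in the knockout in cadmium, MT-CO2 stood at -0.002 and YAP1 at -0.021. With reverse-strand counts, in the difference of the cadmium response, ADAMTSL4 stood at 0.499 and MT-ND6 at 0.117, where the main values count both strands. The cause was not tested for these reversals.

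With an estimated correlation the lists called were 5 for zinc and 5 for cadmium in wild type, 5 for cadmium in the knockout, 3 for the genotypes in water, 2 and 2 for the differences of the zinc and cadmium responses, 0 for cadmium against zinc, and 2 and 1 for the genotypes in zinc and in cadmium. Fry, which does not compare a list with other genes, called 18 (zinc, wild type), 19 (cadmium, wild type), 20 (zinc, knockout), 17 (cadmium, knockout), 16 (genotypes in water), 8 (difference of zinc response) and 18 (cadmium against zinc), and turned the direction of p53 targets for cadmium in wild type (adjusted p = 0.00762) and between genotypes in cadmium (0.000407) and of zinc transporters between genotypes in zinc (0.0405). At least 5 CPM in 3 libraries left 5 lists for the difference of the cadmium response. Leaving out 1 library gave 4 to 7 lists for cadmium against zinc, the latter without wild-type zinc replicate 3. The cause was not tested for these list results.

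Across genes, the correlation of wild type and knockout moved with how many low genes enter: without a filter it was 0.322 for zinc and 0.258 for cadmium, with at least 5 CPM in 3 libraries 0.863 and 0.860, and for cadmium with only the groups of the comparison 0.753. Without each library in turn it ran from 0.7357 to 0.7495 for zinc and from 0.6858 to 0.7046 for cadmium, where a group of fewer libraries lets more low genes pass the filter. That of zinc and cadmium in wild type was 0.584 without a filter. The cause was not tested for the value with only the groups of the comparison. As to depth, the smallest library held 25478614 counts, and MT1G had 2 counts in the water libraries of each genotype.

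Same replicate numbers did not pair the libraries throughout: 15 of 45 same-number pairs had a correlation of residuals over 0.1 (lowest -0.075, median 0.062, highest 0.329), against a median of -0.03 for other pairs, though 16 of 18 libraries had their highest mean correlation with their own number, a hint from the data and not the design. In cadmium against zinc in wild type and in the genotypes in cadmium every same-number pair exceeded 0.1, which was looked at by comparison only after the blocked calls were seen. With a replicate block, the lists called for cadmium against zinc were 6 and not 3, all 635 values of named genes kept their calls, and 5 lists gained one, 3 of them in that comparison, mitochondrially encoded mRNAs in the difference of the zinc response and heat shock genes in that of the cadmium response. The block changed no other call of a named gene or list.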

Other observations

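The test of the stretch of chromosome 15 was chosen only after the result was seen, and the tests of copy number and of other cells were fixed before.

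Some genes answered metal in opposite directions in the genotypes. TRIB1, a pseudokinase that controls protein turnover, fell in zinc from 72.3 ± 0.931 to 34.5 ± 8.58 CPM in wild type and rose from 17.1 ± 0.619 to 57.3 ± 1.15 CPM in the knockout (n = 3). ARC, an immediate early gene of neurons, rose in cadmium from 2.43 ± 0.193 to 6.70 ± 0.833 CPM in wild type and fell from 31.1 ± 0.849 to 10.6 ± 0.0450 CPM in the knockout. In zinc 310 genes were called in opposite directions, in cadmium 269, and the difference of the responses was called for all of them. Of these, 2 in zinc and 1 in cadmium were at 5 CPM or more and changed at least 2-fold in both genotypes, so TRIB1 and ARC are extreme cases.

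In water, 29 genes lay at 5 CPM or more in the knockout and under 0.1 CPM in wild type, and 2 the other way round, the same numbers after thinning all libraries to equal depth. Those in the knockout include BMP2 (58.2 CPM), OLR1 (54.0 CPM), RFX7 (36.4 CPM), TENM1 (22.1 CPM), GSPT2 (16.8 CPM) and CD40 (6.89 CPM), of which TENM1, GSPT2 and CD40 were chosen after their values were seen. By chromosome, the median log2 difference between knockout and wild type in water ran from -0.309 on chromosome 14 to 0.355 on chromosome X, a range of 0.664, against at most 0.232 in 10000 shuffles of genes over chromosomes.

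The 2856 genes at least 2-fold apart between the genotypes in water may have several causes. Broad copy-number change does not account for most: 86.48% of that number (2470 genes) were still 2-fold apart after subtracting the running median of neighbouring genes. Focal changes were not tested. Cells of another type in the knockout libraries would bring their abundant mRNAs, but only 1 of 8 fibroblast and epithelial mRNAs, COL1A1 at 33.8 CPM by library size alone (31.8 CPM as scaled elsewhere), reached the median of 10.45 CPM of the 29 genes, with COL1A2 at 0.0539, DCN at 0.009 and EPCAM at 0.083 CPM. Other markers of both kinds lay above it and above wild type, among them COL5A1 (350 against 23.4 CPM), KRT19 (64.7 against 11.4 CPM) and SFN (20.8 against 1.54 CPM), so the test argues against fibroblasts or epithelial cells with the usual full set of these mRNAs, and cells with only some of them stay open. For NEDD4, RFX7, TEX9 and MNS1 on chromosome 15, loss of the stretch in the wild-type line is a candidate explanation: their level in wild type under metal was at most 0.848% of that in the knockout, and the longest run of such neighbours was 4 genes, against 2 in 10000 shuffled orders of 14742 genes. RNA does not separate loss of DNA from silencing, and the genotype and differences between the lines that arose in culture stay open for the rest.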
